A study of Ovis aries with 42 samples.

How the data were processed

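RNA was sequenced from hypothalamus and pars tuberalis of adult Rasa Aragonesa ewes. Per the labels' protocols, the tissues were frozen in liquid nitrogen, total RNA was extracted from about 0.5 g of tissue with a lipid tissue kit, RNA with an integrity number above 7 went into libraries, and sequencing used the Illumina HiSeq 2000. The authors deposited 1 table of raw counts, whole numbers per Ensembl sheep gene ID, with a column for each of the 42 libraries and 27054 IDs. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic 0.38, HISAT2 2.1.0, SAMtools 1.7, StringTie 1.3.5, DESeq2 and R 3.5.1 were used. The notes give these names with no role or order. The genome build, the annotation release, the handling of strand and the handling of reads shared between paralogs are not given in the sources used here, so counts of near-identical or overlapping genes are uncertain. If counts were derived from transcript coverage, as the presence of an assembler among the tools leaves open, they carry the rounding of that step.

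Every column was matched to its sample by library number, tissue and phase, and there were 0 columns of no sample. All 27054 IDs were unique, and 3463 had 0 counts in every library. Library totals ran from 14649356 to 37726207 counts. The most similar pair of libraries was pars tuberalis luteal library 28 and anestrous library 39, with a correlation of 0.973 across features (features are not independent replicates) and a chi-square of 22.5 per degree of freedom over 17126 features. No columns were identical, so all 42 libraries were kept.

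The reference gene table given with the data (ARS-UI_Ramb_v3.0, 35057 genes) matched 0 of the IDs, and the deposited table gives no names. The 28 gene lists and 13 key genes that were fixed before the data were examined could therefore not be tested, nor could the marker-based covariate for cell makeup, and no cell type is assigned. The rule for named genes, fixed at the same time, asked for gene symbols. It was replaced by IDs alone: where features passed, the 2 with the lowest p in either direction, ranked in the tissue comparison by the test against a 2-fold difference, and where none passed, up to 3 with the lowest p, with at most 2 in either direction and given as values without a call.

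Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust dispersion and robust fit, two-sided). Normalization was TMM, features were kept by filterByExpr with a minimum count of 10, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Phase comparisons used 1 fit per tissue with all 21 libraries, so that the 3 phases share an estimate of the spread. These fits tested 16350 features in the hypothalamus and 16301 in the pars tuberalis, with a common biological coefficient of variation of 43.3% and 31.9%. Differences between tissues, and differences of phase effects between tissues, used all 42 libraries and 17296 features (39.8%). The tissue comparison also used a test against a 2-fold difference (glmTreat). No pairing of tissues by ewe entered these fits, because the labels do not tie libraries to ewes. CPM are counts scaled to the TMM-adjusted library size, and per-library log2 values use a pseudocount of 0.5.

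Other settings, also chosen beforehand, were DESeq2 1.42.0, RLE size factors, no filter on low counts, a filter of at least 1 CPM in 7 libraries, limma-voom with sample weights (limma 3.58.1), a fit of only the phases compared, surrogate variables (sva 3.50.0) and leaving out each library in turn. Added after the results were seen were the share of the 10 largest features as a covariate, leaving out the 20 largest features, leaving out library 15 with that covariate or in the 42-library fit, and a block of library numbers 21 apart in the 42-library fit. Splits of the libraries into groups of the same sizes were drawn at random with a fixed seed, 100 for each phase comparison and 40 for each comparison of the 42-library fit, the real split included.

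The tests were checked on simulated data, in which 200 features were changed by 2-fold or 4-fold in negative binomial counts with the means, dispersions and depths of the real libraries. Features were drawn independently, with no variation shared across them and no outlying library, so false calls and recovery in the real libraries may differ. In the simulated hypothalamus follicular against anestrous comparison of 16350 features, edgeR made 139 calls of which 5 were false, DESeq2 made 183 with 26 false and limma-voom made 127 with 4 false. In the pars tuberalis comparison of 16301 features the calls were 158, 190 and 155, with 6, 29 and 4 false. For the difference between tissues in follicular minus anestrous, over 17296 features, edgeR recovered 29% of 2-fold and 73% of 4-fold changes. The matching of libraries across tissues was tested on 150 simulated features: with shared states 21 of 21 libraries matched their partner first, and with independent states 3 did. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for that step.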

Results

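Gene expression was measured by RNA sequencing in 2 tissues of adult Rasa Aragonesa ewes, a Spanish sheep breed whose females cycle seasonally. The hypothalamus (HT) is the brain region that drives reproductive hormone release, and the pars tuberalis (PT) is the part of the pituitary that wraps the stalk below it and reads the night-time melatonin signal of day length. Ewes were sampled in the luteal phase, when a corpus luteum secretes progesterone, in the follicular phase, when follicles mature before ovulation, or in anestrus, the season without cycles. Each of the 3 phases had 7 libraries in each tissue, which gave 42 libraries in 6 groups. The libraries held between 14649356 and 37726207 counts, with a mean of 24349900 ± 4381570 (SD, n = 42). Between 17356 and 19631 of the 27054 sheep gene IDs had at least 1 count in a library. The table pairs no ID with a gene name, so features are given by ID and no gene family or pathway is described. The labels do not say that the 7 libraries of a group came from separate ewes, so each p-value measures the spread between these samples.

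The first question was how the hypothalamus and the pars tuberalis differ. Averaged over the phases, most features differed between the tissues. Of 17296 features tested, 12965 (75%) differed between the tissues at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 6158 of them higher in the pars tuberalis and 6807 higher in the hypothalamus. TMM scaling takes most features as unchanged, so the near balance of the 2 directions rests in part on that scaling. A test against a 2-fold difference still called 3950 features, 1524 higher in the pars tuberalis and 2426 higher in the hypothalamus. Of these, 90 were over 32-fold higher in the pars tuberalis and 200 were over 32-fold higher in the hypothalamus. The first principal component of log2 CPM (counts scaled to library size) held 53.0% of the variance and separated all 21 hypothalamus libraries from all 21 pars tuberalis libraries.

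**Figure D1:**
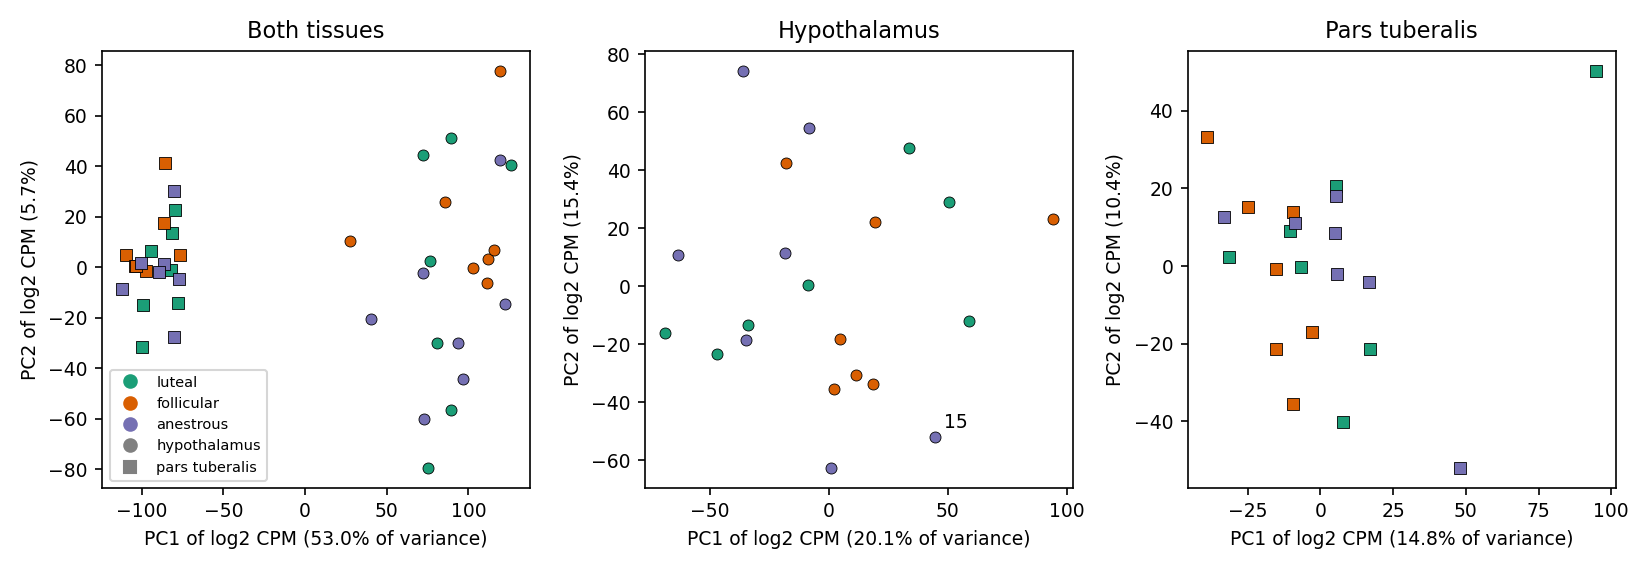
Principal components of log2 CPM for both tissues together (left), the hypothalamus (middle) and the pars tuberalis (right). Each point is 1 library, the colour gives the phase and the symbol the tissue. The tissues separate on the first component (53.0% of the variance), while the phases overlap within each tissue. Hypothalamus anestrous library 15 is marked.

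Among features higher in the pars tuberalis, ENSOARG00000011019 was 13.8-fold higher (log2 fold change 3.78 ± 0.164 SE, adjusted p = 6.69e-22). It lay at 16.8 ± 5.19, 21.1 ± 5.33 and 16 ± 2.95 CPM (SD, n = 7 each) in the luteal, follicular and anestrous pars tuberalis, against 1.5 ± 0.405, 1.29 ± 0.243 and 1.12 ± 0.739 CPM in the hypothalamus. ENSOARG00000005916 was 8.85-fold higher in the pars tuberalis (log2 fold change 3.15 ± 0.131 SE, adjusted p = 1.97e-22), and its luteal level was 36.8 ± 8.51 CPM in the pars tuberalis against 4.40 ± 1.13 CPM in the hypothalamus. Among features higher in the hypothalamus, ENSOARG00000013116 lay at 482 ± 133, 489 ± 189 and 472 ± 128 CPM in the luteal, follicular and anestrous hypothalamus and at 16.9 ± 5.42, 9.37 ± 2.67 and 11.7 ± 2.75 CPM in the pars tuberalis (log2 fold change -5.29 ± 0.163 SE, adjusted p = 4.66e-26). ENSOARG00000007746 showed a log2 fold change of -6.78 ± 0.249 SE (adjusted p = 8.77e-24), with 158 ± 83.9 CPM in the luteal hypothalamus against 1.73 ± 0.667 CPM in the luteal pars tuberalis. For each of these 4 features, every library of one tissue lay above every library of the other, which their choice by the lowest p made likely.

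**Figure D2:**
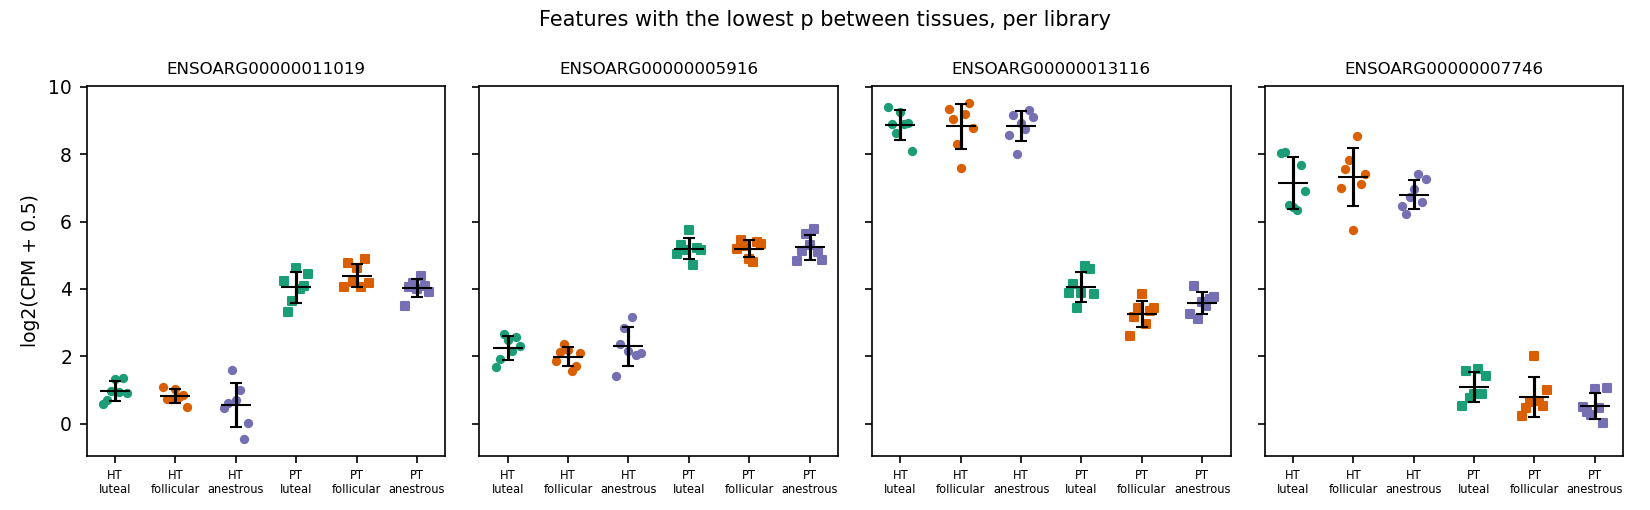
Level of 4 features in each library, as log2 of CPM plus 0.5, by tissue and phase. Points are libraries, and the bars give the mean and SD of the 7 libraries of a group. ENSOARG00000011019 and ENSOARG00000005916 are higher in all pars tuberalis libraries, and ENSOARG00000013116 and ENSOARG00000007746 in all hypothalamus libraries.

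The design then asks how each tissue changes between phases. No feature passed an adjusted p of 0.05 in any of the 6 phase comparisons with edgeR, among 16350 features tested in the hypothalamus and 16301 in the pars tuberalis. Phase accounted for 9.54% of the total variance of log2 CPM in the hypothalamus and 10.8% in the pars tuberalis, against a mean of 10% in each tissue over 100000 permutations of the phase labels (one-sided permutation p = 0.544 and 0.201, Benjamini-Hochberg adjusted p = 0.544 and 0.402 over both tissues). The median standard error of a log2 fold change was 0.253 in the hypothalamus and 0.191 in the pars tuberalis. In simulated counts with the means, spread and depth of these libraries, the same test recovered 53% of 2-fold and 81% of 4-fold changes in the hypothalamus follicular against anestrous comparison, and 64% and 88% in the pars tuberalis. The simulated features were drawn independently and no library was set apart from its group, so these rates may not hold for the real libraries.

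In the hypothalamus, follicular and anestrous libraries differed at an unadjusted p under 0.05 in 1688 features, 686 higher and 1002 lower in the follicular phase, where 5% of the tested features is 818. None passed the adjustment with edgeR (lowest adjusted p = 0.328), while DESeq2 called 72 features (14 higher, 58 lower) and limma-voom with sample weights called 1549 (579 higher, 970 lower). With 5 surrogate variables for the 21 libraries, edgeR called 3. Among these 3, ENSOARG00000009963 had counts in 5 of 7 follicular and 3 of 7 anestrous libraries (highest 236 and 682). Its fitted log2 fold change of 8.14 has no meaning as a size. In the edgeR fit without surrogate variables, the 2 features with the lowest p were both lower in the follicular phase. ENSOARG00000020201 lay at 7.81 ± 2.83 CPM in follicular and 34.4 ± 25.3 CPM in anestrous libraries (SD, n = 7 each; log2 fold change -2.15, 95% interval -3.00 to -1.31, edgeR adjusted p = 0.328). ENSOARG00000014240 lay at 3.85 ± 1.96 and 16.5 ± 10.1 CPM (log2 fold change -2.11, 95% interval -2.98 to -1.24, edgeR adjusted p = 0.328). Both were among the calls of DESeq2 (adjusted p = 0.000364 and 0.00104) and limma-voom (adjusted p = 0.0142 and 0.0165), and neither was among the 3 called with surrogate variables. The count depended on 1 library. Without hypothalamus anestrous library 15, edgeR called 890 of 16419 features, 407 higher and 483 lower in the follicular phase, and 3960 lay at an unadjusted p under 0.05. This count moved with single libraries too. Leaving out 1 further library gave from 29 (without library 16) to 1314 (without library 20). It was 477, 205, 67, 929, 206, 303 and 508 without follicular libraries 8, 9, 10, 11, 12, 13 and 14, and 225, 863, 699 and 240 without anestrous libraries 17, 18, 19 and 21. With the share of counts in the 10 largest features as a covariate it was 281.

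In that fit without library 15, chosen after the results were seen, ENSOARG00000003687 rose to 7.32 ± 1.59 CPM in the 7 follicular libraries from 2.36 ± 0.405 CPM in the 6 remaining anestrous libraries (log2 fold change 1.65 ± 0.212 SE, edgeR adjusted p = 0.00263). ENSOARG00000017537 rose to 108.5 ± 11.2 CPM from 64.1 ± 8.56 CPM (log2 fold change 0.78 ± 0.106 SE, edgeR adjusted p = 0.00332). ENSOARG00000000741 fell to 27.3 ± 3.70 CPM from 52.3 ± 10.7 CPM (log2 fold change -0.93 ± 0.133 SE, edgeR adjusted p = 0.00449). For these 3 features, all 7 follicular libraries lay beyond all 6 anestrous ones. They were picked for a low p in the same libraries, so this separation adds no support. ENSOARG00000013956 fell to 36.5 ± 6.86 CPM from 101.5 ± 42.5 CPM (log2 fold change -1.47 ± 0.233 SE, edgeR adjusted p = 0.00972). Library 15 itself lay on the follicular side of all 4, and past the follicular mean in each. Its values were 9.14, 164.7, 13.7 and 22.6 CPM in the order given. EdgeR called these 4 features without library 15 and not with it.

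**Figure D3:**
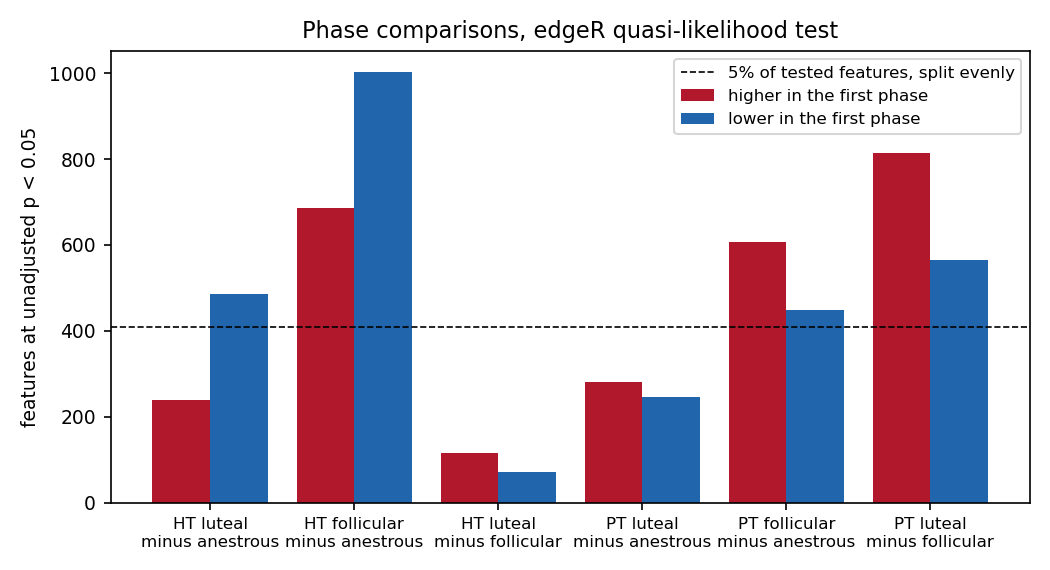
Number of features at an unadjusted p under 0.05 in each phase comparison by edgeR's quasi-likelihood test, split by direction. The dashed line is 5% of the tested features shared equally between the directions. Hypothalamus follicular against anestrous has the largest total (686 higher and 1002 lower), and hypothalamus luteal against follicular the smallest (115 and 71).

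The luteal hypothalamus did not differ detectably from the anestrous one with edgeR (0 called, lowest adjusted p = 0.503, 726 features at an unadjusted p under 0.05 against 818 at 5%). DESeq2 called 3 features, all lower in the luteal phase, limma-voom called 0 and edgeR with surrogate variables called 13. Without library 15, 1752 features lay at an unadjusted p under 0.05 and edgeR still called 0. The lowest p was that of ENSOARG00000016596, at 16.3 ± 2.06 CPM in luteal and 24.8 ± 2.41 CPM in anestrous libraries (SD, n = 7 each; log2 fold change -0.61, 95% interval -0.86 to -0.37, edgeR adjusted p = 0.503). The luteal range of 13.4 to 19.7 CPM did not overlap the anestrous range of 22 to 28.2 CPM. As the feature was picked for the lowest p in these same libraries, that separation adds no support. ENSOARG00000002400 lay at 136 ± 26.6 and 239 ± 76.0 CPM (log2 fold change -0.82 ± 0.191 SE, edgeR adjusted p = 0.993). With surrogate variables both were called (adjusted p = 0.0458 for ENSOARG00000016596 and 0.000422 for ENSOARG00000002400), and DESeq2 called ENSOARG00000016596 (adjusted p = 0.00115).

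Between luteal and follicular hypothalamus, 186 features lay at an unadjusted p under 0.05, 115 higher and 71 lower in the luteal phase, and edgeR, DESeq2 and limma-voom each called 0. With only the 2 compared phases in the fit, the unadjusted count was 576, above the 526 of luteal against anestrous hypothalamus fitted in that way. ENSOARG00000015061 lay at 2.75 ± 0.770 CPM in luteal and 4.65 ± 1.01 CPM in follicular libraries (SD, n = 7 each). ENSOARG00000009381 lay at 3.30 ± 1.89 and 1.48 ± 0.552 CPM, and ENSOARG00000019063 at 1.28 ± 0.409 and 2.68 ± 0.875 CPM. The edgeR adjusted p of each rounded to 1.

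Between follicular and anestrous pars tuberalis, 1055 features lay at an unadjusted p under 0.05 (606 higher and 449 lower in the follicular phase, 815 at 5%), edgeR called 0 (lowest adjusted p = 0.471), DESeq2 called 6, of which 1 had a fitted log2 fold change beyond 10, and limma-voom called 1. ENSOARG00000017381 lay at 55.2 ± 8.92 CPM in follicular and 81.9 ± 10.4 CPM in anestrous libraries (log2 fold change -0.57, 95% interval -0.80 to -0.34). ENSOARG00000011149 lay at 13.3 ± 3.01 and 22.2 ± 4.65 CPM (log2 fold change -0.74, 95% interval -1.05 to -0.42). ENSOARG00000014391 lay at 28.9 ± 25.7 and 7.61 ± 2.72 CPM (log2 fold change 1.92, 95% interval 1.09 to 2.75). All 3 had an edgeR adjusted p of 0.471 and were among the DESeq2 calls (adjusted p = 0.00942, 0.0213 and 0.00484). The 1 feature that limma-voom called, ENSOARG00000026992, had counts in 1 of 7 anestrous libraries and at most 23 counts in a follicular one.

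Luteal against follicular pars tuberalis gave 1380 features at an unadjusted p under 0.05, 814 higher and 566 lower in the luteal phase, and edgeR called 0 (lowest adjusted p = 0.469). DESeq2 called 14 (8 higher, 6 lower), of which 2 had fitted log2 fold changes beyond 10, and limma-voom called 0. ENSOARG00000016672 lay at 9.30 ± 5.32 CPM in luteal and 2.24 ± 0.870 CPM in follicular libraries (SD, n = 7 each; log2 fold change 2.05, 95% interval 1.15 to 2.96, edgeR adjusted p = 0.469). ENSOARG00000026014 lay at 33.7 ± 11.9 and 10.4 ± 4.82 CPM (log2 fold change 1.69, 95% interval 0.94 to 2.44, edgeR adjusted p = 0.469). DESeq2 called both (adjusted p = 0.00471 for each).

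Luteal against anestrous pars tuberalis gave 526 features at an unadjusted p under 0.05, fewer than the 815 that 5% makes, and edgeR and limma-voom called 0 while DESeq2 called 4. Of these 4, 3 had counts in at most 2 of the 7 libraries of either phase, and their fitted log2 fold changes of 22.4, -21.1 and -22.5 have no meaning as sizes. ENSOARG00000004936 lay at 7.53 ± 1.71 CPM in luteal and 11.6 ± 2.39 CPM in anestrous libraries, ENSOARG00000015730 at 3.42 ± 0.772 and 5.80 ± 1.17 CPM, and ENSOARG00000013616 at 93.0 ± 30 and 52.3 ± 13.5 CPM (SD, n = 7 each, edgeR adjusted p = 0.999 for all 3).

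The last comparison asks whether a phase difference itself differs between the tissues. No feature passed in the 42-library edgeR fit for luteal minus anestrous, follicular minus anestrous or luteal minus follicular. At an unadjusted p under 0.05 there were 719, 1154 and 552 features, against 865 at 5%. DESeq2 called 10, 30 and 3 features, of which 6, 3 and 3 had fitted differences beyond 10 on the log2 scale, and limma-voom called 0 in each. Without library 15, edgeR called 47 features for follicular minus anestrous (40 with a higher difference in the pars tuberalis, 7 with a lower one) and 0 for the other contrasts.

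The follicular minus anestrous contrast came nearest to the threshold, with an edgeR adjusted p of 0.0582 for its 3 leading features, which DESeq2 called (adjusted p = 0.0010, 0.000543 and 0.000441 in the order below), as did edgeR without library 15 (adjusted p = 0.00735, 0.00735 and 0.0195). ENSOARG00000001727 lay at 25.2 ± 6.62 CPM in the follicular and 14.2 ± 4.46 CPM in the anestrous hypothalamus, and at 4.50 ± 1.55 and 8.28 ± 2.86 CPM in the pars tuberalis (difference of log2 fold changes -1.70 ± 0.327 SE). ENSOARG00000020185 lay at 13.2 ± 7.40 and 169 ± 235 CPM in the follicular and anestrous hypothalamus and at 46.7 ± 30.2 and 24.8 ± 7.84 CPM in the pars tuberalis (difference 4.59 ± 0.906 SE). ENSOARG00000018621 lay at 6.36 ± 4.18 and 87.7 ± 119 CPM in the hypothalamus and at 21.7 ± 33.2 and 6.84 ± 6.04 CPM in the pars tuberalis (difference 5.44 ± 1.09 SE). The anestrous hypothalamus libraries spread from 6.35 to 637 CPM for ENSOARG00000020185 and from 5.39 to 328 CPM for ENSOARG00000018621. Without library 17 their means there were 91.4 ± 124 and 47.6 ± 57.7 CPM (SD, n = 6), and without library 30 the follicular pars tuberalis mean of ENSOARG00000018621 was 9.18 ± 3.59 CPM. Library 15 held the lowest anestrous hypothalamus values of ENSOARG00000020185 and ENSOARG00000018621 (6.35 and 5.39 CPM) and the highest of ENSOARG00000001727 (22.8 CPM). Leaving it out was bound to widen these differences, so the calls without library 15 add no support to those of DESeq2.

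For luteal minus anestrous (edgeR adjusted p = 0.510 for both features named, DESeq2 adjusted p = 0.0293 and 0.032), ENSOARG00000003561 lay at 3.82 ± 0.585 and 5.63 ± 1.97 CPM in the luteal and anestrous hypothalamus and at 8.91 ± 3.71 and 5.65 ± 1.34 CPM in the pars tuberalis. ENSOARG00000010117 lay at 71.4 ± 6.72 and 94.8 ± 18.8 CPM in the hypothalamus and at 82.3 ± 46.3 and 47.1 ± 7.89 CPM in the pars tuberalis, where luteal libraries 22, 23 and 24 held the high values and the luteal median was 49.2 CPM. For luteal minus follicular (edgeR adjusted p rounding to 1), ENSOARG00000007327 lay at 4.53 ± 1.11 and 5.12 ± 1.26 CPM in the luteal and follicular hypothalamus and at 4.89 ± 4.03 and 1.74 ± 0.265 CPM in the pars tuberalis. ENSOARG00000002400 lay at 136 ± 26.6 and 148 ± 31.9 CPM in the hypothalamus and at 106 ± 134 and 21.8 ± 4.99 CPM in the pars tuberalis. The same 3 luteal libraries carried that mean of ENSOARG00000002400, which was 61.6 ± 68.1 CPM without library 24 (SD, n = 6) beside a median of 22.4 CPM. ENSOARG00000026783 had 1.57 ± 0.652 and 1.42 ± 0.764 CPM in the luteal and follicular hypothalamus, 0 counts in all 7 luteal pars tuberalis libraries and 0.177 ± 0.197 CPM in the follicular ones, so no fold is given.

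The makeup of the libraries varied within groups. The 10 largest features of a library took between 14.8% and 43.0% of its counts, with a mean of 30.1 ± 7.75% in the hypothalamus and 22.9 ± 5.37% in the pars tuberalis (SD, n = 21 each). One feature, ENSOARG00000009137, took between 0.00687% and 18.6% of the counts in the hypothalamus and between 0.01% and 6.11% in the pars tuberalis. Its median share was 0.785% in luteal, 1.74% in follicular and 0.571% in anestrous hypothalamus, and 2.28%, 0.102% and 2.81% in the pars tuberalis.

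**Figure D4:**
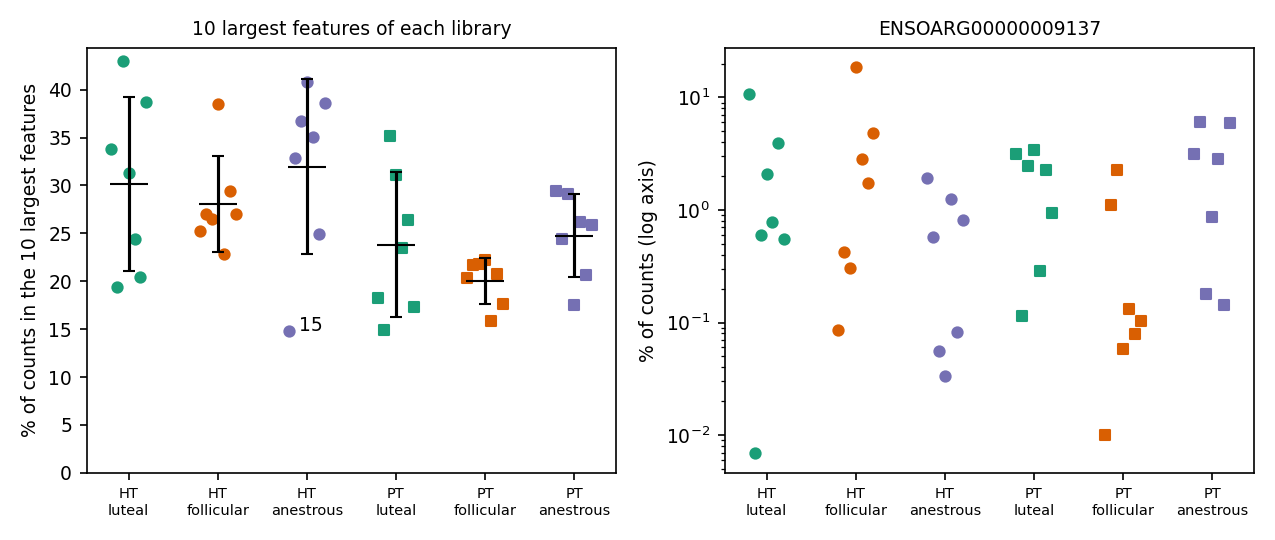
Share of each library's counts in its 10 largest features (left, with mean and SD of 7 libraries) and in ENSOARG00000009137 alone (right, log axis), by tissue and phase. The left axis starts at 0. Hypothalamus anestrous library 15 has the lowest share on the left (14.8%), and the right panel runs from 0.00687% to 18.6%.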

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

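All tests in this part other than the outlier checks and the planned splits of the libraries were chosen after the results were seen. Among 109 groups of 7 values, 13 held a value set apart from the others by Dixon's criterion (critical ratio 0.568). For normally distributed values chance flags about 1 in 20, or 5.5. Hypothalamus anestrous library 15 had the highest total of its group, 33586399 counts against 21483731 to 25123805 in the others, and the most detected features, 19631 against 17583 to 18389. Pars tuberalis anestrous library 36 had the lowest total, 14649356 counts against 25019148 to 28376173. In hypothalamus follicular library 11 the 10 largest features took 38.5% of the counts, against 22.9% to 29.5% in the others.

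Single features also stood apart on the scale of log2 CPM plus a pseudocount. ENSOARG00000019063 lay at -0.0616 in hypothalamus luteal library 5 (others 0.71 to 1.12), and ENSOARG00000010117 at 5.86 in hypothalamus luteal library 7 (others 6.09 to 6.27). Pars tuberalis luteal library 24 held ENSOARG00000003561 at 4.15 (others 2.83 to 3.18) and ENSOARG00000007327 at 3.84 (others 1.27 to 2.30). ENSOARG00000020185 lay at 4.91 in hypothalamus follicular library 14 (others 3.04 to 3.8). ENSOARG00000018621 lay at 6.60 in pars tuberalis follicular library 30 (others 1.89 to 3.74) and at 4.39 in pars tuberalis anestrous library 38 (others 2.17 to 2.73).

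The first pattern is the 890 features that edgeR called between follicular and anestrous hypothalamus when library 15 is left out, against 0 with it, where 887 of the 890 kept their direction at a median absolute log2 fold change of 0.499 (median SE 0.224). The 2 fits share every other library, so that kept direction was largely fixed beforehand and is no support for the calls. Without library 15, 1 of 100 splits of the 13 libraries, the real one, called as many as 890, and the highest other split called 2. Library 15 was the only 1 of 21 libraries whose removal gave any call, and the other splits had no such search. Chance is therefore not excluded for a count that rests on that choice. A difference in library makeup cannot be told apart from phase as part of the cause: with the share of the 10 largest features as a covariate 281 features were called, 207 of them among the 890, and the median absolute log2 fold change of the 890 went from 0.71 to 0.61 (85.8% of its size) at a median SE of 0.178 and 0.180, while what ended the other calls was not tested apart from the degree of freedom the covariate takes. Pars tuberalis tissue that sets library 15 apart is argued against by the summed CPM of 90 pars tuberalis features. These were picked in the same libraries, library 15 included, so the list is not independent of it. Their summed CPM was 15.9 in library 15, inside the range of 5.35 to 403.6 of the other hypothalamus libraries, and 4212 on average in the pars tuberalis. The mean of those other hypothalamus libraries, 76.6, was raised most by libraries 5, 11, 16 and 17. Among the remaining anestrous libraries it was 185.4 and 403.6 in libraries 16 and 17, and 7.625 to 26.72 in libraries 18 to 21. Whether such tissue in the remaining libraries bears on the 890 calls was not tested. A wrong phase label stays open, as does a real difference of that sample. On the axis of the 890 features, with makeup held at its mean, library 15 scored 0.0625. Follicular libraries scored -0.999 to -0.373, luteal ones -1.485 to -0.659 and the other anestrous ones -2.712 to -1.5. Library 15 thus lay above every other hypothalamus library and inside the range of no phase. Its score decides neither, since edgeR called those features in the fit without library 15.

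The second pattern is ENSOARG00000009137, which took 18.6% of the counts in hypothalamus follicular library 11 (others 0.0867% to 4.88%) and 10.6% in luteal library 1 (others 0.00687% to 3.92%). Both were set apart in their groups by Dixon's criterion on the percentages themselves. The criterion was not applied to these shares on a log scale, where the outcome may differ. A varying amount of cells of another kind in the tissue pieces may account for this pattern, but was not told apart from other causes. Across the hypothalamus libraries, 30 further features followed it with a rank correlation above 0.8. The 29 of them tested in the pars tuberalis followed it there with a median of 0.41, above all 10000 random lists of the same level (median -0.253, highest -0.0234). All of those lists lay below 0, so a list with a median correlation of 0 would also exceed them. The random lists were not chosen to move together, so the median of 0.41 shows a set that moves together in both tissues and not why. The kind of cell is left open, because no ID was matched to a name here. Reproductive phase cannot be told apart from chance here: permuting the phases gave a p of 0.382 (adjusted 0.382) in the hypothalamus and 0.0358 (adjusted 0.0717) in the pars tuberalis, where geometric means were 10750 CPM in luteal, 1327 CPM in follicular and 12830 CPM in anestrous libraries (permutation test, n = 7 each), and the p-values do not show that the phases were alike.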

How the results depend on the processing

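The alternatives that left out library 15 from more than a phase fit, used the 10 largest features as a covariate, dropped the 20 largest features or used a block were chosen after the results were seen. All phase counts of 0 stayed at 0 with RLE size factors, without the low-count filter, with the stricter filter, with only the compared phases, with the covariate and without the 20 largest features. DESeq2 moved luteal minus anestrous, follicular minus anestrous and luteal minus follicular to 3, 72 and 0 in the hypothalamus, 4, 6 and 14 in the pars tuberalis and 10, 30 and 3 for the difference between tissues. In the simulations, which drew features independently and held no outlying library, DESeq2 made more false calls than edgeR. Limma-voom with sample weights gave 1549 for hypothalamus and 1 for pars tuberalis follicular minus anestrous, and surrogate variables gave 13 for hypothalamus luteal minus anestrous and 3 for follicular minus anestrous. The cause of these differences was not tested. Leaving out each library in turn gave 0 to 890 calls for hypothalamus follicular minus anestrous, where only library 15 gave any, and 0 to 0 in the other phase comparisons. Without library 15 and with the covariate it was 281, and leaving out library 15 with 1 more gave 29 to 1314. The difference between tissues in follicular minus anestrous was 47 without library 15. The tissue count stayed within 1.5 times of 12965, from 12964 with RLE to 14236 without a filter. Of 529 values of the 27 named features and comparisons, 505 kept direction and side, 24 passed the threshold and 0 reversed. These features were picked for a low p in the same libraries, so a reversal was unlikely beforehand. For features without a call, the same side means only that they stayed without one. The labels pair no libraries across tissues. Numbers 21 apart were tried as a replicate block, although 3 of the 21 pairs correlated at 0.1 or less (0.002, 0.084 and -0.037) and 18 matched their own number first. With it the 3 differences between tissues stayed at 0 called (lowest adjusted p for follicular minus anestrous 0.0699) and the tissue count was 13037. The gene list tests and the marker covariate were not run, because no ID matched a name. A depth of at least 14649356 counts went with a common coefficient of variation between libraries of 43.3% in the hypothalamus and 31.9% in the pars tuberalis.

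As every real count of calls was 0, all 100 splits reached it by construction in each of the 6 phase comparisons, which decides nothing about chance. The highest other counts were 65, 3 and 315 for hypothalamus luteal minus anestrous, follicular minus anestrous and luteal minus follicular, and 153, 2 and 2 in the pars tuberalis, while 4, 3 and 3 of the 99 other splits in the hypothalamus and 3, 3 and 5 in the pars tuberalis called any. Splits with 65, 315 or 153 calls leave room for a structure of the samples other than phase, which was not tested. Chance was not excluded for the counts at an unadjusted p under 0.05: 56, 10 and 79 of 100 splits reached the real 726, 1688 and 186 in the hypothalamus (highest other 3233, 4011 and 3574), and 58, 18 and 16 reached 526, 1055 and 1380 in the pars tuberalis (highest other 2678, 2583 and 2397). Without library 15, 1 of 100 reached the 3960 of follicular minus anestrous (highest other 2981). For the differences between tissues, all 40 splits reached 0, again by construction, with highest others of 53, 8 and 0, and these splits ignore any pairing of the libraries. For the tissues themselves, 1 of 40 splits, the real one, reached 12965 and the highest other called 1. The other splits mix 2 tissues that differ widely, which raises the spread within groups, so few calls there were likely beforehand. These 40 splits alone therefore do not exclude chance.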

Other observations

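All tests in this part were chosen after the results were seen. Features that are high in the pars tuberalis also appeared in some hypothalamus libraries. The summed CPM of the 90 features over 32-fold higher in the pars tuberalis ran from 5.35 in hypothalamus luteal library 2 to 403.6 in anestrous library 17, and was 318.2 in follicular library 11, 237.6 in luteal library 5 and 185.4 in anestrous library 16, against 2519 to 5806 in the pars tuberalis libraries.

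The third pattern concerns library numbers. Over 135 features that were switch-like in both tissues (their libraries fell into a low and a high set), hypothalamus libraries 1 to 21 and pars tuberalis libraries numbered 21 higher had a mean correlation across features of 0.224 after removal of phase means, where 100000 permutations within phases gave a mean near 0 (permutation p = 1e-05, the smallest they can give). Of the 21 hypothalamus libraries, 18 matched their partner number best among the 7 of their phase, where chance gives 3, and libraries 7, 12 and 20 did not, while stricter limits on the switch gave 16 (67 features) and 14 (27 features). A candidate explanation is that both tissues of a pair came from the same ewe, with inherited differences that switch features on or off in both. Shared handling of the pairs cannot be told apart from this: 0 of 1000 lists of features without a switch, matched on level and spread, correlated as strongly (median 0.134, highest 0.203), but their median SD was 0.689 against 0.781 for the switch-like features, so the matching was not complete, and 10600 features without a switch also correlated, at 0.115 (permutation p = 0.0004, 10 of 21 matched best), as shared handling would give too. The labels state no such pairing, and it entered only the replicate block tried in the 42-library fit.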
